A study of Homo sapiens with 12 samples.

How the data were processed

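Total RNA of HUH6 cells given NT siRNA (6 samples) or GATA4 siRNA (6 samples) was biotin-labelled and hybridised to Illumina HT-12 v4 beadchips, per the labels. The deposited scanner table gives a linear signal intensity per probe and array, read out with GenomeStudio per the submitters' processing notes, which give no version; its lowest value is 82.2, so no background had been subtracted. Per the file headers, a detection p-value stands beside each signal, and on all 12 arrays it fell with that array's own signal. The deposited normalised table holds log2 values; the authors' method is not given in the sources used here, and the values differ by at most 0.0141 from a quantile normalisation of the log2 signals. The deposited series table holds the same log2 values (largest difference 0). No column was left without a sample.

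Probes were named from the platform annotation, with symbols updated through gene IDs in a RefSeq table of GRCh38.p14, used for names and gene classes only (30073 probes matched, 47 kept the older symbol). Of 48106 probes, 30112 have 1 gene symbol, 8 have several and 17986 have none. Probes without a single symbol were counted apart.

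Signals were background-corrected with the background inferred from the detection p-values, offset by 16, quantile normalised and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. A probe was tested where its detection p was under 0.01 on at least 6 of the 12 arrays: 16339 probes passed, 13201 of them with 1 symbol. The tested probe with the highest mean signal stood for its gene, giving 10196 genes. Of the 203 genes called with the replicate block that have over 1 tested probe, 179 had all probes in 1 direction and 4 had another probe with p under 0.05 in the other. Groups were compared with lmFit and eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Gene lists with at least 5 tested genes were compared with camera (preset correlation 0.01, and an estimated one). For GATA4, which was not above background after GATA4 siRNA, the fold is a bound: the NT siRNA mean against the mean, per array, of the higher of the lowest detected signal and the probe's own.

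The design, the 26 gene lists, the 6 lists of cell type markers and the alternatives were fixed before the data were examined. By rule the text names GATA4, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (uncharacterised loci left out), up to 3 higher and 3 lower called members of each list, or else the member with the lowest p, all tested GATA family members, and ACTB and GAPDH. The rule was repeated on the fit with the replicate block after the data were seen. List symbols with no tested probe were not analysed here. The results of 1 list and of some genes the rule names are not reported here.

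The labels number the replicates 1 to 6 in both groups. Samples of the same number deviated together from their group means (Pearson's r over genes 0.548 to 0.604), so the numbers were taken to pair the samples. Samples of different numbers within replicates 1 to 3 or within 4 to 6 correlated as much (0.549 to 0.629), and about the means of group and set the same-number values were -0.0604 to 0.0119. The pairing therefore comes from 2 sets of arrays, for which the labels and files give no chip, date or batch. No 2 arrays held identical values; Pearson's r between arrays was 0.979 to 0.996. The median SD of a gene was 0.161 within groups and 0.107 within groups and sets.

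The tests were tried on simulated data with each gene's spread within groups and sets. Noise was drawn independently for each gene and array. The false calls therefore do not measure the effect of correlation between genes or of shared cultures or array runs. In the comparison of GATA4 siRNA with NT siRNA over 10196 genes without a block, 14.9% of genes changed by 0.25 on the log2 scale were recovered, 67.2% of those changed by 0.5 and 90.9% of those changed by 1, with 1 false call of 116. With the replicate block the shares were 46.3%, 86.6% and 100%, with 5 false calls of 160. Alternatives changed the background correction and normalisation, the source of the values, the filter, the probe rule, the variance model (robust fits with statmod 1.5.0), array weights and the block, and left out each sample in turn. The block by chip could not be run.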

Results

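HUH6 is an established human hepatoblastoma cell line, derived from a malignant liver tumour of early childhood. The cells were transfected with a pool of siRNAs against GATA4, a zinc finger transcription factor of endoderm, heart and gonad development, or with a non-targeting (NT) control siRNA, each at 0.1 uM for 6 h. RNA was taken 72 h after the start of transfection and hybridised to expression beadchips, 6 arrays per group. On the 12 arrays, 16067 to 16804 of 48106 probes were detected, and 10196 named genes were tested. The median raw signal was 117.4 to 121.2 on the NT siRNA arrays and 120.8 to 128.1 on the GATA4 siRNA arrays. The number of arrays limits the precision. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples.

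GATA4 itself was lower in all 6 samples given GATA4 siRNA. Its probe read 137.1 to 168.8 raw units in the NT siRNA samples, with detection p-values of 0 to 0.00909. After GATA4 siRNA it read 108.3 to 119.3, with detection p-values of 0.25195 to 0.73766, so it was not above background in any sample of that group. The mean log2 signal was 5.69 ± 0.33 (SD, n = 6) with NT siRNA and 4.49 ± 0.078 (SD, n = 6) with GATA4 siRNA. Set against the mean of the lowest detected signals per array (5.43), the NT siRNA mean was at least 1.19-fold higher. This bound is on group means, without their sampling error, and NT siRNA replicate 4 (5.42) lay below that level. The fitted log2 fold change was -1.20 (SE 0.15, limma adjusted p = 0.00122), and an exact two-sided permutation test of the 6 against 6 samples gave p = 0.00216, the smallest it can give. The other tested members of the GATA family and its cofactors did not pass the threshold with or without the replicate block. ZFPM1 passed with the 2 sets of replicates 1 to 3 and 4 to 6 as blocks (adjusted p = 0.0471) and within replicates 4 to 6 (log2 change 0.44, adjusted p = 0.0263). GATA6 had a log2 change of 0.24 (SE 0.099, adjusted p = 0.43), ZFPM1 of 0.30, GATA2 of 0.13 and GATA5 of 0.11. Adjusted over the list alone, 2 of the 5 members were higher and 1 was lower, which was GATA4 itself. Its own low p eases that adjustment for the other members.

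The comparison asks which transcripts change when GATA4 is silenced. In limma, 20 genes were higher and 52 were lower after GATA4 siRNA at an adjusted p under 0.05. By fitted fold, 0 of these were higher and 2 were lower by at least 2-fold, GATA4, for which the data bound the fold only at 1.19, and DNAH2. On the authors' normalised values 0 were lower as much. On the neqc values, 0 genes were higher by at least 2-fold at an unadjusted limma p under 0.05. Scaling the arrays to equal medians in place of quantiles gave 2 higher and 21 lower. The 12 arrays also parted by replicate number in both groups: the first principal component, with 57.3% of the variance, separated replicates 1 to 3 from replicates 4 to 6, and the second, with 9.66%, separated the siRNAs. The sets were defined after this was seen. With the replicate number as a block, 270 genes were higher and 384 lower, among them all 72 genes called without it. Within replicates 1 to 3 alone 60 were higher and 107 lower, and within replicates 4 to 6 alone 209 were higher and 342 lower. Between these sets, which share no control sample, 91 genes were called in both and in the same direction and 0 in opposite directions. Independent lists of these lengths would share 1.23 higher and 3.59 lower genes, against 24 and 67 observed. A limma test of whether the change after GATA4 siRNA differed between the sets called 0 genes, with 901 at an unadjusted p under 0.05. The 0 does not show that the changes were equal in both sets.

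**Figure D1:**
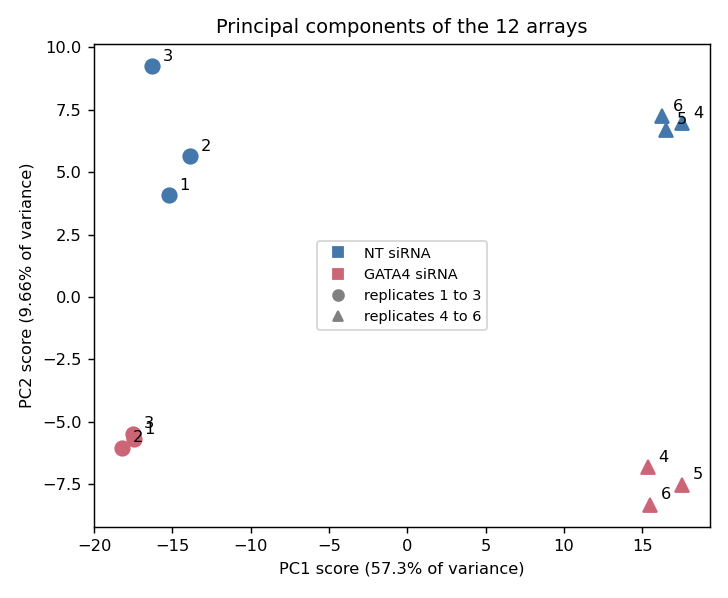
Scores of the 12 arrays on the first (x axis, 57.3% of variance) and second (y axis, 9.66% of variance) principal components of the log2 signals of 10196 genes. Colour gives the siRNA, shape the set of replicates and the digit the replicate number; the sets part along the x axis and the siRNAs along the y axis.

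The largest falls after GATA4 siRNA were ranked among called genes whose groups do not overlap. This selection puts all 6 GATA4 siRNA samples below all 6 NT siRNA samples in each gene. The genes were DNAH2, HNRNPH3, FN1, NCAPG2, LBH, LEPROTL1, DCUN1D4, COPG1 and SLIT3, beside GATA4. DNAH2, an axonemal dynein heavy chain, was 2.15-fold lower (log2 change -1.10, SE 0.17, adjusted p = 0.00462). HNRNPH3, an RNA-binding protein of the nucleus, was 1.85-fold lower (log2 change -0.89, SE 0.088, adjusted p = 0.000154), and its second probe read -0.89 too. FN1, which encodes fibronectin of the extracellular matrix, was 1.78-fold lower (log2 change -0.83, SE 0.15, adjusted p = 0.0203), with -0.84 and -0.77 at its other probes. NCAPG2, a condensin II subunit, changed by -0.82, LBH, a transcriptional cofactor, by -0.78, and SLIT3, a secreted guidance ligand, by -0.66 (-1.03 at its other probe). LEPROTL1 changed by -0.73, DCUN1D4, a factor in cullin neddylation, by -0.70 (-0.27 at its dimmer probe) and COPG1, a subunit of the coatomer of transport vesicles, by -0.69. Adjusted p-values of these 6 genes ran from 1.66e-05 to 0.00334. The call of FN1 without the block ended on leaving out any of 4 samples. The groups did not overlap in 171 genes, where free exchange of the 12 samples gives 22.1 (0.216%). Exchange within the sets of arrays only, over the 199 other splits, gave a mean of 7.94 and at most 38.

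The largest rises, ranked in the same way, were smaller, at log2 changes of 0.37 to 0.55. By that selection all 6 GATA4 siRNA samples lay above all 6 NT siRNA samples. DSTYK, a protein kinase, was 1.46-fold higher (log2 change 0.55, SE 0.059, adjusted p = 0.000348), with 0.58, 0.36 and 0.0074 at its other probes. POLE3, a subunit of DNA polymerase epsilon, rose by 0.49 (adjusted p = 0.00334). ERP27, a chaperone-like protein of the endoplasmic reticulum, rose by 0.54 and UBD, a ubiquitin-like modifier, by 0.40, both with an adjusted p of 0.0438. CACNA2D4, an auxiliary subunit of calcium channels, rose by 0.45, NACC2, a transcriptional repressor, by 0.43, EPDR1 by 0.41 and USH1C, the scaffold protein harmonin, by 0.37. The other probes of NACC2 and USH1C read 0.021 and 0.097. RPL23AP32, a transcribed pseudogene whose probe can also bind RNA of its parent gene family, rose by 0.51 (adjusted p = 0.0462). Leaving out 1 sample ended the calls without the block of UBD for 11 of the 12 samples, of ERP27 and RPL23AP32 for 10, of CACNA2D4 for 8 and of NACC2 for 2. With the replicate block, and among genes whose groups do not overlap, UTS2B (0.44, adjusted p = 0.0128) joined the 10 largest rises in place of USH1C, while the 10 largest falls were the same genes. Among all genes called with the block, some whose groups overlap changed more, such as CTNNB1 (-0.75).

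**Figure D2:**
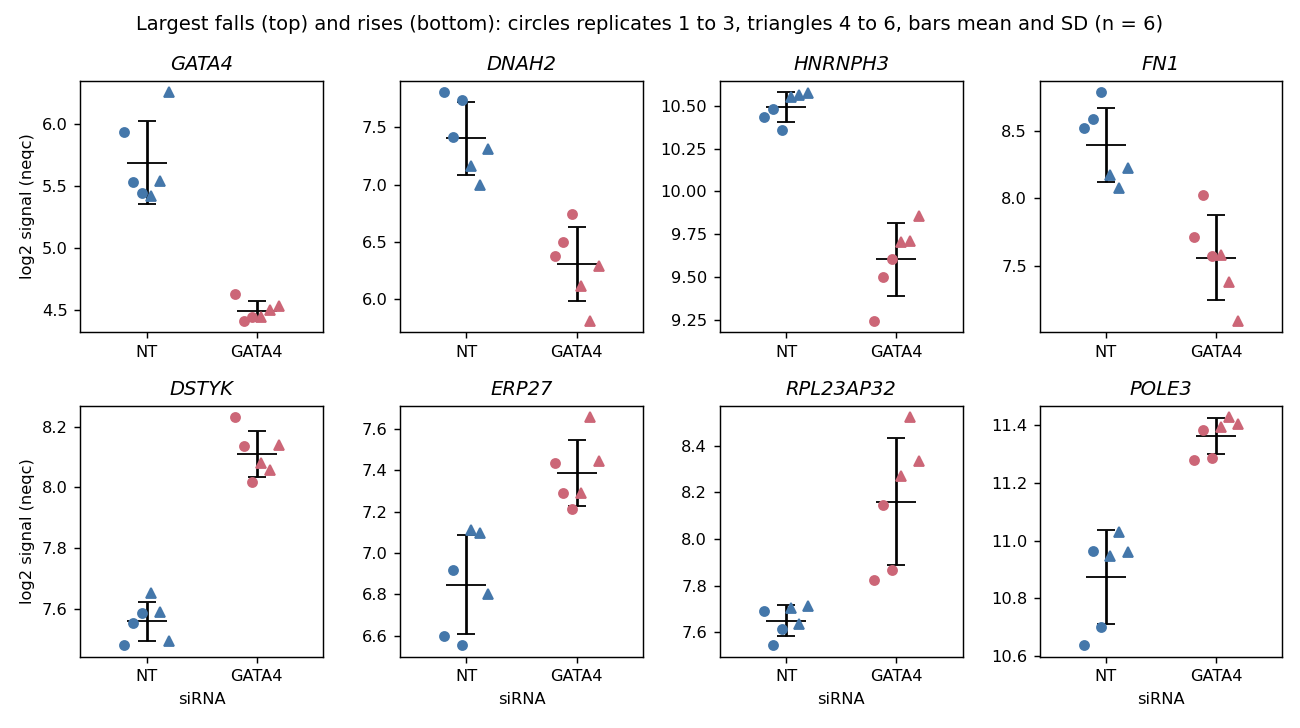
Log2 signal (y axis, background-corrected and quantile normalised) in each of the 12 samples for the 4 largest falls (top) and the 4 largest rises (bottom), by siRNA (x axis). Circles are replicates 1 to 3 and triangles 4 to 6, with bars for the mean and SD of 6 samples. These genes were selected as ones whose 2 groups do not overlap. The GATA4 siRNA values of GATA4 are not above background.

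Over all tested genes the replicate block called 654 of 10196, to be set beside the list counts that follow. Single liver genes were called in both directions. Of 48 plasma proteins made by hepatocytes, 0 passed without the block, and with it 3 were higher and 5 lower (5 and 5 adjusted over the list alone). With the block, F2 (prothrombin) was -0.49 (SE 0.092, adjusted p = 0.00176), ALB (albumin) -0.23 (adjusted p = 0.0058) and FGG (fibrinogen gamma) -0.19, while AGT (angiotensinogen) was 0.20 and F12 (coagulation factor XII) 0.24. Of 24 genes of liver metabolism and detoxification, SULT2A1, the sulfotransferase of steroids and bile acids, fell in both fits (-0.41, SE 0.082, adjusted p = 0.0361), although its call without the block ended on leaving out any of 9 samples. The block gave 3 higher and 4 lower in that list, with HPD (0.31) and FAH (0.21) of tyrosine breakdown and ASS1 (0.18) of the urea cycle higher, and GSTA1 (-0.24) and CPS1 (-0.22) lower. Of 14 hepatocyte transcription factors, 0 passed without the block (0 higher and 2 lower adjusted over the list alone) and 2 were lower with it, CREB3L3 (-0.34, adjusted p = 0.00719) and FOXA2 (-0.15, adjusted p = 0.0366). Within replicates 1 to 3 alone 0 of these 14 were called lower, and within replicates 4 to 6 alone 3 were. Of 20 fetal liver and hepatoblast markers, 0 passed without the block and 4 were lower with it, among them PEG3 (-0.33), DUSP9 (-0.31) and SALL4 (-0.21). ECI2, an isomerase of unsaturated fatty acid oxidation, fell in both fits (-0.63, SE 0.081, adjusted p = 0.00146; its other probe -0.67) and was the 1 gene of 17 of that pathway to pass. Of 21 genes of cholesterol synthesis and 14 of fatty acid synthesis, 0 passed with or without the block; the lowest p without it were those of ACAT2 (-0.091) and FASN (-0.081), and with it of LSS (-0.12) and SCD (-0.095).

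Single genes of cell junctions and matrix were also called in both directions, mostly with the block only. FN1 was the 1 of 17 mesenchymal genes called without the block. With it, AXL (0.34), TAGLN (0.24) and COL1A2 (0.22) were higher beside the fall of FN1. Of 37 basement membrane, matrix and integrin genes, 0 passed without the block, with TIMP2 at the lowest p (-0.32, and -0.047 at a dimmer probe), and 3 were higher and 3 lower with it. COL4A2 (0.42), LAMA5 (0.22) and COL12A1 (0.23) were the higher ones, and ITGA6 (-0.45), TIMP2 and FBN2 (-0.17) the lower ones. Of 32 epithelial junction genes, 0 passed without the block, and with it CLDN3 (0.32) and MARVELD3 (0.22, with 0.0028 and -0.059 at its other probes) were higher and CDS1 (-0.30) lower. These 3 lists also differed between the sets of arrays by camera with the preset correlation: their median log2 difference, replicates 4 to 6 minus 1 to 3, was -0.54 for mesenchymal, -0.20 for matrix and -0.19 for epithelial genes. With an estimated correlation the matrix and epithelial lists passed between the sets (adjusted p = 0.031 and 0.0324) and the mesenchymal list did not (adjusted p = 0.0686).

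Among signalling lists, 0 genes passed without the block. CTNNB1, which encodes beta-catenin, was -0.75 (SE 0.12, adjusted p = 0.000342 with the block and 0.0964 without it), and -0.63 at its other probe. Of 29 Wnt and beta-catenin genes, 4 were higher and 3 lower with the block; CD44 (0.28), NKD2 (0.20) and ZNRF3 (0.18) were higher and TCF7L2 (-0.33) and DKK1 (-0.14) lower beside CTNNB1. Adjusted over the list alone without the block, 0 were higher and 2 lower. Of 17 TGF-beta and BMP genes, TGFBR2 (0.20) was higher and FST (-0.33), BMP2 (-0.29) and PMEPA1 (-0.28) were lower with the block, and adjusted over the list alone without it 1 was higher and 2 were lower. Of 18 YAP and TEAD targets, F3 (0.42), AXL and FJX1 (0.22) were higher and ANKRD1 (-0.30) and CRIM1 (-0.28) lower with the block. That list had a median of -0.54 between the sets of arrays.

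Single S phase genes were called in both directions. Of 45 S phase genes, E2F2, a transcription factor of S phase entry, rose (0.31, SE 0.061, adjusted p = 0.0335), a call that ended on leaving out any of 10 samples, and with the block RRM2 (0.29) joined it while 5 were lower, among them MCM2 (-0.23), POLA1 (-0.22) and MCM4 (-0.18). Of 50 genes of G2 and mitosis, 0 passed without the block and ANLN (-0.20, adjusted p = 0.0261) was lower with it. Of 26 p53 targets, CDKN1A (0.24) was higher and BAX (-0.28, with -0.079 at its dimmer probe) lower with the block, and BAX was the 1 of 29 apoptosis regulators to pass. IRF9 (0.35, adjusted p = 0.0166) was the 1 of 21 interferon response genes to pass with the block, and 0 of 16 NF-kB and acute phase genes did, NFKBIA having the lowest p (-0.16). Of 36 ATF4 and unfolded protein response genes SHMT2 (0.15) was higher and NUPR1 (-0.26) lower, and of 36 hypoxia and glycolysis genes SLC2A1 (0.27) and PFKP (0.20) were higher and P4HA1 (-0.28) and PFKFB3 (-0.26) lower, all with the block. Of 7 tested cardiac and gonadal genes tied to GATA4, 0 passed in either fit, with AMHR2 (-0.12) at the lowest p without the block and TNNC1 (0.17) with it. AGO1 (-0.32, adjusted p = 0.0141) and TNRC6A (-0.25) of the 11 siRNA machinery genes were lower with the block. Among 15 reference genes, TFRC (-0.24) and YWHAZ (-0.16) were lower with the block, while ACTB (-0.055, adjusted p = 0.81) and GAPDH (-0.0065, adjusted p = 0.997) did not pass in either fit.

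**Figure D3:**
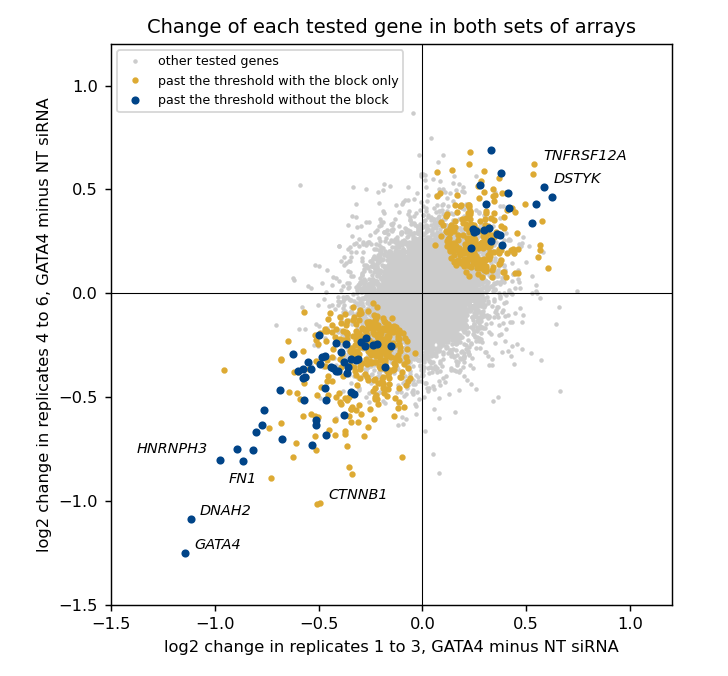
Log2 change after GATA4 siRNA of each of 10196 genes in replicates 1 to 3 (x axis) and in replicates 4 to 6 (y axis), which share no samples. Blue points are the 72 genes called without the block and yellow ones those called only with it; the 91 genes called in each set separately have the same direction in both, and Pearson's r over genes, which are not independent replicates, was 0.375.

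As whole lists, 0 of 29 passed limma's camera test with a preset correlation of 0.01, and 2 had an unadjusted p under 0.05, those of G2 and mitosis (lower, adjusted p = 0.48) and siRNA machinery (lower, adjusted p = 0.55). With an estimated correlation 0 passed and 0 had an unadjusted p under 0.05. With the replicate block 5 had an unadjusted p under 0.05. Of these, G2 and mitosis (lower, adjusted p = 0.137), macrophages (higher, adjusted p = 0.288), and fetal liver and siRNA machinery (both lower, adjusted p = 0.288) did not pass. The markers of stellate cells and fibroblasts, 6 of which were tested, passed as higher (adjusted p = 0.0394), with TAGLN and COL1A2 called. That list did not pass with an estimated correlation (adjusted p = 0.68), and its median differed by -0.63 between the sets of arrays. Of the other markers, 0 of 9 cholangiocyte genes (lowest p ANXA4, -0.17, without the block and CFTR, -0.16, with the block), 0 of 7 macrophage genes (CD74, 0.11, without the block and CD68, 0.19, with the block), the 1 endothelial gene (PECAM1, -0.11) and 0 of 3 lymphocyte genes (CD3D, 0.078) passed in either fit, and 0 erythroid genes were tested. PDGFRB (0.16) had the lowest p of the stellate cell markers without the block. Within replicates 1 to 3 alone, 1 of the 9 cholangiocyte genes was called lower, and within replicates 4 to 6 alone 0 were.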

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

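The tests of the sets of replicates by cell type and of the scaling between arrays were chosen after the results were seen; the tests of brightness, background correction and other splits were written down before their results. Among 108 named genes, 216 groups of 6 samples were looked at for a sample far from the others by Dixon's ratio of gap to range, and chance gives about 10.8. There were 4: USH1C in NT siRNA replicate 5 (7.14 on the log2 scale, the others 7.28 to 7.32), CTNNB1 in NT siRNA replicate 1 (8.10, the others 8.85 to 9.18), GAPDH in NT siRNA replicate 4 (13.62, the others 13.46 to 13.51) and TCF7L2 in GATA4 siRNA replicate 4 (6.72, the others 7.02 to 7.21). Among detected probes without a single gene symbol, which enter no comparison of the report, 1 was higher and 7 were lower after GATA4 siRNA, and 58 and 43 with the replicate block.

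The widest pattern is that replicates 1 to 3 differ from replicates 4 to 6 in both groups. With the siRNA in the fit, 2637 genes were higher and 2570 lower in replicates 4 to 6, 45 and 115 of them by at least 2-fold. Fibroblasts or stellate cells among the cells of replicates 1 to 3 are not settled by the share of their markers detected there. It was 46.7% of those named on the array, under a cut set after the results were seen. COL3A1 (4.59), DCN (4.75) and LUM (4.47), abundant in such cells, were at background there, which argues against cells that express them. ACTA2 (12.42), TAGLN (12.31) and COL1A2 (10.16) were bright there, but also in replicates 4 to 6 (11.85, 11.57 and 9.48). RGS5 (8.34 against 7.25) and PDGFRB (8.27 against 8.03) were also lower in replicates 4 to 6, while PDGFRA was higher (5.52 against 6.33). Array brightness or background stays open, since 36.9% of the genes that differ at least 2-fold lie among the dimmest quartile of genes, between the bounds set for either answer. Separate cultures, passages or array runs were not tested, because nothing in the labels or files tells them apart, and besides a mixture of cells no biological explanation was tested.

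Falls after GATA4 siRNA were larger than rises: with the replicate block, 23 genes were lower and 0 higher by at least 1.5-fold, and 84.3% of the 102 most extreme changes were falls. Background correction as the whole cause is argued against, since with the authors' table, which has none, 80.4% of the most extreme changes were falls (10 lower and 0 higher by at least 1.5-fold). Scaling between arrays stays open, since the values differ: with equal medians 81.4% were falls, and with no scaling 52.0% (18 lower and 4 higher by at least 1.5-fold), but there all genes shift with the brightness of the arrays (median log2 change 0.0554). Silencing of GATA4 and binding of the siRNAs to other transcripts both stay open and were not tested.

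Other splits of the 12 samples were counted, with the split by sets placed among the 100 because that structure had been seen. For the 20 higher genes and for the 52 lower genes, 2 of 100 splits gave as many. They were the real one and the split of replicates 1 to 3 from 4 to 6 (up to 2431 in 1 direction). This argues against chance exchange of these samples apart from that structure. The other splits called at most 7 genes in all. For the 2 genes lower by at least 2-fold as fitted, the same 2 splits gave as many (highest other 115). The difference between the sets, 4818 genes without a block, was reached by 1 of 100 splits, its own (highest other 72). That rank tests nothing, since the sets were defined after the arrays were seen to part in this way. Of the 32 splits parting all 6 pairs, the real one alone gave as many as 270 higher or 384 lower genes (highest other 0). The others differ from it by exchanging the siRNAs within some pairs. A share of 1 of 32 is the smallest this test can give, and it argues against chance exchange of these samples. The labels do not say whether replicates came from separate cultures, so chance between cultures is not excluded. For the 1 gene list past the set test with the block, 5 of 32 splits gave as many (highest other 2), so chance is not excluded. For the 0 lists without it 100 of 100 did (highest other 16), which tests nothing, since any split gives at least 0. Within replicates 1 to 3 (167 genes, highest other 1) and within 4 to 6 (551 genes, highest other 0), the real split alone of 10 gave as many, and 10 splits are too few for a share under 0.05.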

How the results depend on the processing

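The set block, the fits within a set and the combinations with the replicate block were chosen after the data were seen. GATA4 kept its direction and its side of the threshold in all settings that tested it (log2 change -1.25 to -0.42); with detection asked on all 12 arrays it was not tested. Higher and lower genes, 20 and 52, became 270 and 384 with the replicate block, 335 and 449 with the set block, 60 and 107 in replicates 1 to 3 alone, 209 and 342 in replicates 4 to 6 alone, 2 and 21 with equal medians, and 9 higher with no filter, where more genes are tested; leaving out 1 sample gave 7 to 17 higher and 28 to 40 lower, with fewer samples. The higher genes were over 1.5 times fewer without NT siRNA replicate 1, 2, 3, 4 or 6 (9, 9, 7, 12 and 10) or GATA4 siRNA replicate 1, 2, 4, 5 or 6 (12, 8, 10, 8 and 9), and the lower ones without NT siRNA replicate 1, 2, 3 or 6 (34, 33, 28 and 33) or GATA4 siRNA replicate 1, 4 or 5 (33, 33 and 34). Genes lower at least 2-fold, 2, were 0 on log2 raw signals, the authors' table or the series table, which have no background correction, 1 with detection on all 12 arrays and 4 in replicates 4 to 6 alone. The 0 lists past the set test became 1 with the replicate block, the set block or in replicates 1 to 3 alone, and 0 to 1 on leaving out 1 sample (1, G2 and mitosis, lower, without NT siRNA replicate 3 or GATA4 siRNA replicate 4, 5 or 6). With an estimated correlation 0 lists passed with all samples, with or without the replicate block; the other settings were not run with one. The 270 genes higher with the replicate block and the 384 genes lower with the replicate block became 131 and 231 with equal medians, 153 and 245 with no filter and 104 and 167 without the variance trend, and 169 to 244 and 263 to 352 on leaving out 1 sample (178, 173, 176 and 169 higher without NT siRNA replicate 4 or 6 or GATA4 siRNA replicate 4 or 6). Where no reason is given, the cause was not tested.

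Of 1431 values of 53 other named genes, 1271 kept direction and side, 92 lost the threshold, 53 gained it and 15 turned, all 15 in genes that did not pass: ACAT2 (0.027 with the mean of probes), ANXA4 (0.072 in replicates 4 to 6), GAPDH (0.010 with the mean of probes, 0.051 with every probe, 0.00062 with array weights, 0.0030 in replicates 1 to 3, and 0.0060 to 0.019 without NT siRNA replicate 4 or GATA4 siRNA replicate 2, 3 or 5) and CD3D. Over the left-out samples the GAPDH log2 fold change ran from -0.036 to 0.019 and the CD3D log2 fold change from -0.032 to 0.18, below 0 without NT siRNA replicate 4, 5 or 6 or GATA4 siRNA replicate 2 or 3. Of genes past the threshold, leaving out 1 sample ended the calls of UBD, ERP27, RPL23AP32, E2F2, SULT2A1, CACNA2D4, FN1 (without NT siRNA replicate 1, 2 or 3 or GATA4 siRNA replicate 5, adjusted p up to 0.0579) and NACC2 (without NT siRNA replicate 3 or 6, up to 0.0539); their adjusted p reached at most 0.116, and directions stayed. Of 753 list tests, 93 had the other direction, none of them past the threshold in the fit without a block. The variance model does not enter the set test. Signal over background limits GATA4, whose fold is a bound.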

Other observations

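The genes in this part and the test of RNA classes were chosen after their values were seen. The sets of arrays were also defined from these same arrays, so p-values between them describe a split already seen. Between the sets of arrays, the largest differences included COL6A3, a collagen VI chain, higher in replicates 4 to 6 by 2.62 on the log2 scale (SE 0.076), with FBLN2 (1.55), LMO2 (1.57) and BHMT (1.61), and SIGLEC6 (-2.20), LRP2 (-2.19), NPPB (-2.01), C4BPB (-1.85), HSD3B1 (-1.77) and CFI (-1.76) lower, all with limma adjusted p-values of at most 2.99e-11. Of the 29 lists, 15 passed camera between the sets, and 9 with an estimated correlation. Genes of G2 and mitosis were higher in replicates 4 to 6 (35 of 50 higher and 1 lower, adjusted p = 0.00919 with an estimated correlation), as were S phase genes (26 of 45 higher and 1 lower, adjusted p = 0.0318 with an estimated correlation). Lower there were ATF4 and unfolded protein response genes (28 of 36 lower and 3 higher, adjusted p = 0.00244 with an estimated correlation), YAP and TEAD targets (16 of 18 lower and 1 higher), p53 targets (18 of 26 lower and 2 higher), interferon response genes (14 of 21 lower and 3 higher) and cholesterol synthesis genes (13 of 21 lower and 1 higher), each of these 4 lists with an adjusted p of 0.0318 with an estimated correlation.

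With the replicate block, genes outside the lists that changed after GATA4 siRNA included TNFRSF12A, the receptor of the cytokine TWEAK (0.58, SE 0.063, adjusted p = 3.45e-06), CFI, complement factor I (0.55), MYH11, a smooth muscle myosin (-0.81, adjusted p = 5.43e-05), IGFBP1, a secreted binding protein of insulin-like growth factors (-0.76, adjusted p = 1.01e-05), and SYTL2 (-0.65). None of these 5 passed without the block.

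As groups, ribosomal and small nuclear RNAs were not tested for a shift after GATA4 siRNA. All 3 ribosomal RNAs had values below 0 (median -0.55; 0 passed without the block and 2 with it, RNA28SN5 at -0.56 and RNA18SN5 at -0.55), as did all 7 small nuclear RNAs (median -0.17; 0 passed without the block and 2 with it). With equal medians and with the authors' table the same 3 and 7 were below 0 (medians -0.54 and -0.16, and -0.26 and -0.12). A lower share of all RNA without a poly(A) tail may be a candidate explanation. Small nucleolar RNAs (29 of 53 below 0, median -0.037) and replication histones (13 of 18 below 0, median -0.059) together had a median 0.191 above that of the ribosomal and small nuclear RNAs, less than their own interquartile range of 0.202, so the test does not decide.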
